A study of Arabidopsis thaliana with 9 samples.

How the data were processed

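Polyadenylated RNA of Arabidopsis thaliana seedlings was sequenced in 9 strand-specific libraries on a DNBSEQ instrument, with 3 libraries each of Col-0, of the mutant melinoe and of Col-0 treated with riboflavin. The deposited data are a table of mutant against Col-0 with 24242 genes and a table of riboflavin against Col-0 with 24249 genes, and both hold the same Col-0 libraries. Per the submitters' processing notes, Bowtie2, RSEM and DESeq2 were used with the TAIR10 genome, with no versions given. The design text of the series instead names SOAPnuke 1.5.2 for read filtering and HISAT2 2.0.4 for alignment, so which aligner gave the values is not settled by the labels.

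Per the file headers, the authors give expected counts of reads for each gene and library, not normalized. Of these deposited counts, 1.88% were not whole numbers, and they were rounded here before testing. The deposited TPM values, per the file headers, are scaled for length and depth by the authors; their 12 columns for single libraries were not used here. The deposited log2 fold changes and the deposited p-values and q-values of each comparison are the authors' own, per the file headers, and the method of adjustment is not stated. These fold changes and p-values were used here only to set the authors' calls beside the calls made here.

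The tables were joined by gene identifier into 24635 genes, 23856 of them in both. The 386 genes found only in the mutant table and the 393 found only in the riboflavin table had no read in any Col-0 library, and they were set to 0 in the group whose table lacks them. All 24635 identifiers matched the TAIR10.1 annotation, from which positions were taken. The tables hold no gene of the plastid or mitochondrial genome, so transcripts encoded in the organelles were not analysed here. Library totals ran from 19964402 to 21421421 counts.

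Each comparison used its own 6 libraries in edgeR 4.0.16 under R 4.3.3. Genes with too few reads were removed by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and the quasi-likelihood F test was applied with no covariate. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Expression levels are given as CPM on the TMM scale, as mean ± SD over the 3 libraries of a group, and fold changes are edgeR estimates with a prior count of 0.125.

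The 31 gene lists analysed hold 443 loci, of which 441 are in the tables, and they were written from general knowledge before the data were examined, as were the comparisons, the tests, the rule for naming genes and most alternatives. Genes ranked by fold change were limited to called genes with no overlap between the libraries of the groups and a mean of at least 100 counts in the higher group, so genes with fewer reads and larger fold changes are not among them. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. The test was repeated with an estimated correlation and with fry. The test with a preset correlation treats genes of a list as nearly independent, whereas an estimated correlation lowers its power.

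Alternatives were DESeq2 1.42.0, DESeq2 size factors or upper quartile scaling in edgeR, no filter on low counts, a mean count of at least 50, all 9 libraries in 1 fit, the column letters A to C as a block, a log2 fold change of at least 1, and leaving out each library in turn. After the data were seen, a fit with a smooth trend on GC content and transcript length removed, and limma-trend on the log2 of counts per transcript length plus 1, scaled to the same sum in each library, were added. The column letters could not be matched to the replicate numbers of the labels, and libraries with the same letter in different groups shared no deviation from their group means, with correlations across genes from -0.0231 to 0.038.

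Data were simulated from these libraries with 50 genes changed at each fold. For mutant against Col-0, edgeR recovered 58% of genes changed by 1.25-fold, 88% at 1.5-fold and 92% at 2-fold, and called 9 unchanged genes in a set of 20277 genes in all. For riboflavin against Col-0 it recovered 54%, 86% and 88%, with 14 unchanged genes called. Far fewer genes were changed there than were called in the data, so these numbers of false calls do not carry over to the data. Of the lists moved in the simulations, 2 of 2 were called in each comparison, and none of the others was. The simulated genes were drawn independently of each other, so this cannot show how often unmoved lists of correlated genes would be called.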

Results

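RNA of 6-day seedlings was measured in 3 groups of 3 libraries. Col-0 is the wild type. The mutant, melinoe, is an EMS-mutagenised line altered in FMN/FHY, the gene of a bifunctional enzyme that phosphorylates riboflavin to FMN and also hydrolyses FMN. The riboflavin group is Col-0 given riboflavin, the vitamin from which the flavin cofactors FMN and FAD are made, for 8 hours of the dark period. The sample labels state a dose of 0.6 mM and the design text 0.2 mM, and neither says at what hour untreated Col-0 and mutant seedlings were collected or whether untreated plants had a mock treatment.

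Library totals were 20972520 to 21421421 counts in Col-0, 19964402 to 20818013 in the mutant and 20677749 to 21103222 in the riboflavin group. CAB1, a chlorophyll a/b-binding protein of the light-harvesting antenna, had the most counts of any gene in every Col-0 and mutant library. It held 1.17% to 1.24% of counts in Col-0 and 0.929% to 0.971% in the mutant. In every riboflavin library NIT1, a nitrilase, had the most, with 0.503% to 0.538%. These counts are not scaled for transcript length, and the split of reads between CAB1 and its paralogs is uncertain. The correlation of log2 CPM across genes was at least 0.995 between libraries of a group and at most 0.972 between groups. Genes are not independent replicates, so this correlation describes similarity only.

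**Figure D1:**
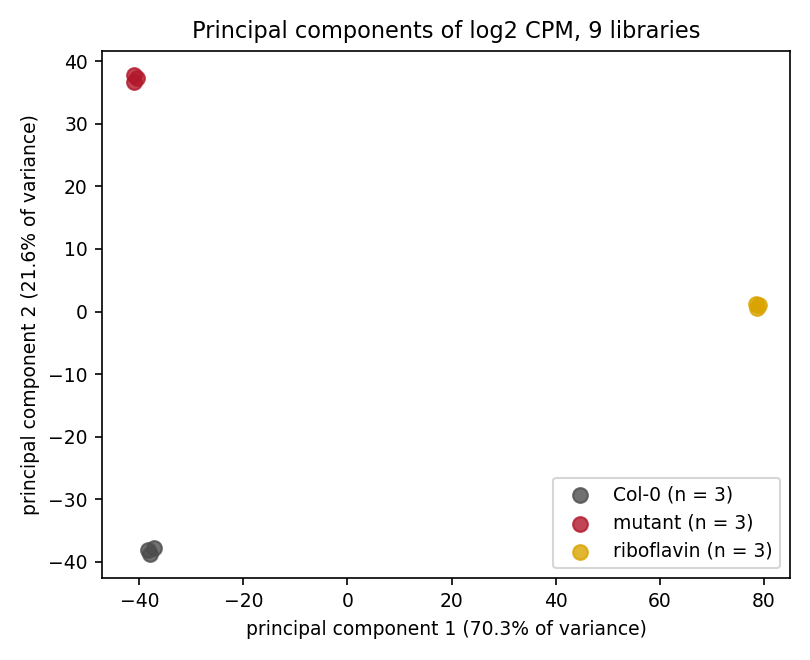
Principal components of log2 CPM in the 9 libraries, each point a library coloured by group. The first component holds 70.3% of the variance and parts the riboflavin libraries from the others, and the second, with 21.6%, parts the mutant from Col-0.

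The comparison of riboflavin-treated with untreated Col-0 asks how wild-type seedlings responded to exogenous riboflavin. It cannot part riboflavin from the hours of dark during the treatment, since the hour at which untreated Col-0 was collected is not given. Transcripts of the mitochondrial stress response and of detoxification enzymes rose together, while those of the photosynthetic apparatus and of glucosinolate synthesis fell. All 19 measured members of the mitochondrial stress list were higher, with a median log2 fold change of 3.101, and so were all 19 of the xenobiotic detoxification list, with a median of 2.79. All 28 antenna, photosystem and RuBisCO genes were lower, with a median of -1.42. Of 20356 genes tested, 7494 were higher and 7604 lower, of which 1567 at least doubled and 2024 at least halved (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The share of calls that were higher was 49.6%, and it was 44.5% with upper quartile scaling.

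FMN/FHY (AT4G21470; TAIR10.1 chromosome 4, 11431104 to 11433322, 10 exons) rose 2.66-fold with riboflavin. Its level went from 42.0 ± 2.26 CPM in Col-0 to 112 ± 1.63 CPM (SD, n = 3), a log2 fold change of 1.41 with a standard error of 0.045 (edgeR quasi-likelihood, adjusted p = 1.98e-20). Its counts were 860 to 950 in the Col-0 libraries and 2284 to 2332 in the riboflavin libraries. Of the 13 genes of flavin metabolism, 5 rose, 5 fell and 3 did not pass. AT4G11570 (PYRP2), a phosphatase of the riboflavin pathway, rose by a log2 fold change of 1.05. Smaller rises were measured for RIBA2 (0.30) and GCH, also called RIBA1 (0.18), which encode enzymes of the first steps of the pathway, and for NUDX23 (0.24), an FAD pyrophosphohydrolase. Other pathway members fell: riboflavin synthase AT2G20690 had a log2 fold change of -0.63, lumazine synthase COS1 -0.55, and the deaminase PyrD and its partner AT3G47390 (PHS1) -0.55 and -0.44, while the FMN hydrolase FHY1 had -0.34. The list as a whole was not called (camera, adjusted p = 0.673), and its median of -0.10 and its test had opposite signs.

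Among flavoprotein photoreceptors, the blue-light receptors phototropin 1 and 2 fell and the other members rose. PHOT1 (AT3G45780) went from 382 ± 2.46 to 145 ± 5.14 CPM, a log2 fold change of -1.40, and PHOT2 had -0.64, whereas LKP2, an F-box photoreceptor of the clock, had 0.41. Of the 7 members, 5 were higher and 2 lower, and the list was not called (camera, adjusted p = 0.616), with a positive median and a test in the negative direction.

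**Figure D2:**
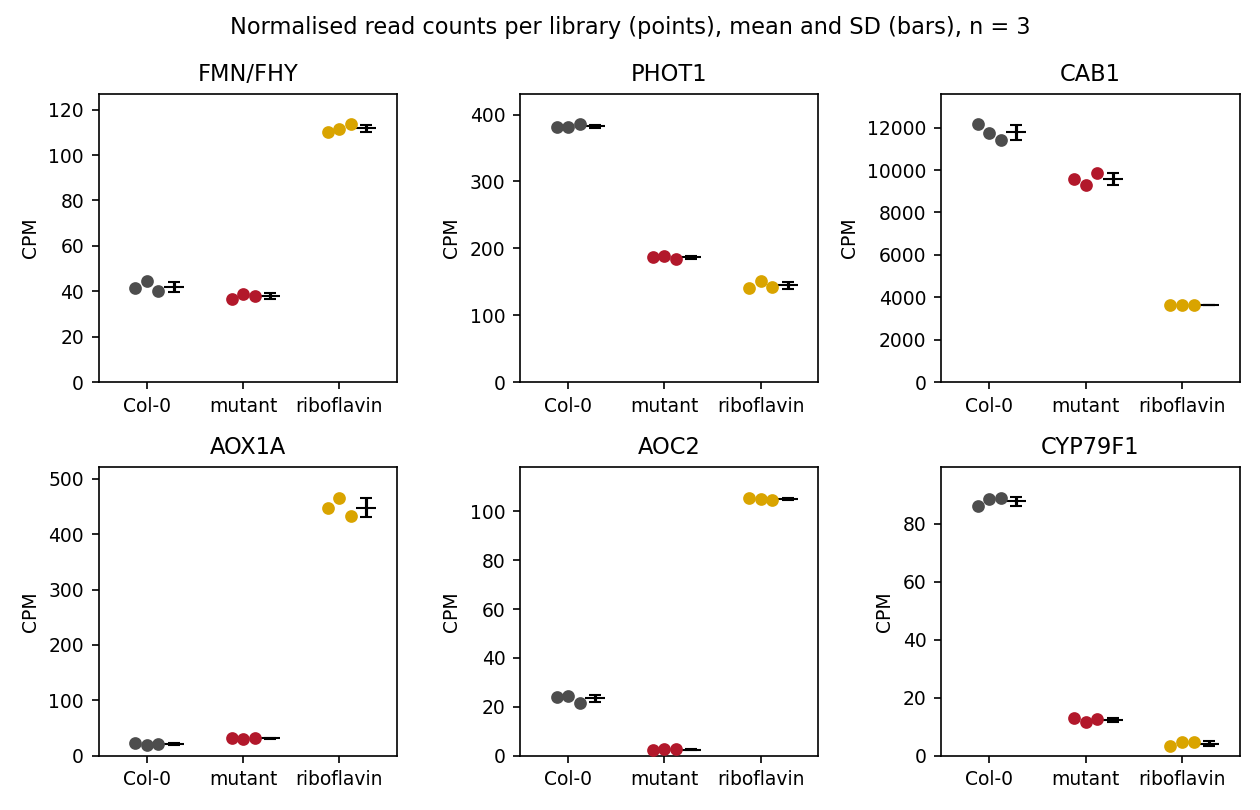
CPM of 6 genes in each library, with points for the 3 libraries of a group and bars for mean and SD, on axes that start at 0. FMN/FHY is at 42.0 CPM in Col-0, 37.9 in the mutant and 112 with riboflavin; AOX1A rises most with riboflavin, and AOC2 lies below Col-0 in the mutant and above it with riboflavin.

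In the mitochondrial stress list, AOX1A (AT3G22370), the alternative oxidase that bypasses part of the respiratory chain, rose from 21.5 ± 1.75 to 448 ± 16.6 CPM, a log2 fold change of 4.38 (edgeR quasi-likelihood, adjusted p = 5.46e-30). UGT74E2, a glucosyltransferase acting on indole-3-butyric acid, rose by 6.28 and the sulfotransferase SOT12 by 4.75. The list passed with the preset correlation (camera, adjusted p = 2.97e-45) and with an estimated correlation (camera, adjusted p = 0.00149). For xenobiotic detoxification, a list of glutathione S-transferases, glycosyltransferases, cytochromes P450 and oxophytodienoate reductases, camera gave adjusted p = 1.98e-65 with the preset correlation and adjusted p = 0.0014 with an estimated correlation. GSTU8 in that list had a log2 fold change of 2.30 and GSTF6 1.31. Heat shock proteins and factors were mostly higher, with 14 of 17 higher, 2 lower and a median of 1.58 (camera, adjusted p = 3.51e-10; adjusted p = 0.0204 with an estimated correlation). HSP17.6A rose by 4.03 and the chaperone HSP90.1 by 1.58; reads of the small heat shock genes, which are close paralogs, are uncertain in their assignment.

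Genes of the photosynthetic apparatus fell without exception among the 28 measured (camera, adjusted p = 2.32e-43; adjusted p = 0.0204 with an estimated correlation). RBCS1B, a RuBisCO small subunit, went from 205 ± 17.2 to 16.8 ± 1.47 CPM, a log2 fold change of -3.60. The antenna genes CAB3 and CAB2 had -2.48 and -2.41. These RBCS and CAB genes have near-identical paralogs, so the split of reads among them is uncertain. Of 20 genes of chlorophyll biosynthesis, 19 fell and 1 did not pass, with a median of -0.99 (camera, adjusted p = 1.20e-14; adjusted p = 0.0727 with an estimated correlation). Plastid gene expression had 9 of 14 members lower and 3 higher, with a median of -0.59 (camera, adjusted p = 0.00655; adjusted p = 0.222 with an estimated correlation).

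Senescence and chlorophyll breakdown genes were higher in 8 of 8 cases, with a median of 0.94 (camera, adjusted p = 6.95e-07; adjusted p = 0.0660 with an estimated correlation). The senescence marker SAG13 rose by 4.50, NYE1, which removes magnesium from chlorophyll a, by 1.88, and the pheophytinase PPH by 0.86. Dark- and starvation-induced genes were higher in 15 of 18 cases and lower in 2, with a median of 0.55 (camera, adjusted p = 4.93e-11; adjusted p = 0.0261 with an estimated correlation). DIN2 (AT3G60140), a dark-inducible beta-glucosidase, went from 4.2 ± 0.32 to 725 ± 6.86 CPM, a log2 fold change of 7.43. Another beta-glucosidase, BGLU28 (AT2G44460), had the highest log2 fold change among called genes with a mean of at least 100 counts in the higher group and no overlap between the libraries of the groups, 9.81, from 0.22 ± 0.10 to 199 ± 3.57 CPM. The other 4 genes at the top were SUC7, a sucrose-proton symporter with close paralogs whose reads are uncertain, at 7.24, and AT2G38823, AT3G54530 and AT5G24640, of unknown function, at 7.29, 7.12 and 6.77.

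Glucosinolate genes fell in 11 of 14 cases and rose in 2, with a median of -1.27 (camera, adjusted p = 5.35e-13; adjusted p = 0.02004 with an estimated correlation). CYP79F1 (AT1G16410), which makes aldoximes from chain-elongated methionine in aliphatic glucosinolate synthesis, went from 87.8 ± 1.59 to 4.18 ± 0.82 CPM, the lowest log2 fold change among called, non-overlapping genes with a mean of at least 100 counts in the higher group, at -4.39. MYB29, a transcription factor of the aliphatic branch, had -3.94. The other 4 genes at that end were PIL1, a shade-induced transcription factor, at -4.08, the transcription factor gene AT1G33760 at -4.09, the peroxidase AT5G19890 at -3.85 and AT4G29030 at -3.72.

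Growth-related lists were also lower. Cell cycle genes fell in 16 of 17 cases, with a median of -1.23 (camera, adjusted p = 4.14e-05; adjusted p = 0.0727 with an estimated correlation). Auxin genes fell in 17 of 20 cases and rose in 3, with a median of -1.14 (camera, adjusted p = 0.00278; adjusted p = 0.119 with an estimated correlation). IAA19, an auxin-induced repressor of auxin response, had -2.83 and the auxin efflux carrier PIN7 -1.72, while GH3.3, which conjugates auxin to amino acids, had 1.39.

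Among nutrient lists, phosphate starvation genes were higher in 12 of 16 cases and lower in 4 (camera, adjusted p = 0.0122; adjusted p = 0.222 with an estimated correlation). Nitrate genes were higher in 7 of 13 cases and lower in 4 (camera, adjusted p = 0.00472; adjusted p = 0.127 with an estimated correlation). Iron storage was not called (camera, adjusted p = 0.396), although the ferritin FER1 rose by 2.00 and the metal transporter YSL1 by 0.80 and AT3G25190 fell by 0.92 on the log2 scale. Jasmonate genes went both ways, 12 higher and 7 lower of 19, and the list was not called (camera, adjusted p = 0.0711). The jasmonate biosynthesis genes AOC2, AOC1 and LOX2 rose by 2.17, 1.89 and 1.097, and reads of the paralogs AOC1 and AOC2 are uncertain in their assignment. All 8 morning clock genes were higher, PRR9 by 0.93, CCA1 by 0.50 and PRR7 by 0.49, but the list was not called (camera, adjusted p = 0.0543) except without Col-0 library A (camera, adjusted p = 0.0461). Of the 8 evening clock genes, 6 were higher and 1 lower (camera, adjusted p = 0.426); PRR5 rose by 2.91, and the 0.19 of ELF3 lost its call with upper quartile scaling, at 0.12, and without riboflavin library A, where it was 0.13 (edgeR quasi-likelihood, adjusted p = 0.0532, from 3.53e-04 to 0.0532 over the alternatives).

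Among markers of other tissues, 4 of 6 root hair markers were lower and 2 higher, 4 of 8 endodermis and root tip markers lower, and 2 of 7 stomatal lineage markers lower. Camera, which tests a list against the other genes, called none of these lists, with adjusted p = 0.624, 0.624 and 0.708. In all, camera called 13 of 30 lists, 7 higher and 6 lower, and 6 of these calls held with an estimated correlation. Counts adjusted over the list alone were equal to those above except for endodermis and root tip markers with 3 lower and stomatal lineage markers with 1 lower. Median, mean and test also differed in sign for antioxidant enzymes, reactive oxygen markers, ethylene, flavonoid, iron deficiency and iron storage genes, none of which was called. The groups did not overlap in 75.6% of genes tested, where chance gives 10%. The authors' deposited table has 13685 genes at a q-value under 0.05, and 13452 of the genes called here are among them, with no opposite sign.

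The comparison of the mutant with Col-0 asks how untreated seedlings of the melinoe line, altered in FMN/FHY, differed from the wild type. Most jasmonate genes fell, as did 8 of 11 reactive oxygen markers, with 1 higher, and most detoxification genes rose. Of 19 jasmonate genes, 17 were lower, with a median log2 fold change of -1.04, and of 18 detoxification genes 14 were higher, with a median of 0.60. Of 20277 genes tested, 5148 were higher and 5106 lower, but only 744 at least doubled and 486 at least halved (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The share of calls that were higher was 50.2%, and it was 46.8% with upper quartile scaling and 39.4% with limma-trend on length-scaled counts without TMM.

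FMN/FHY itself was at 37.9 ± 1.26 CPM in the mutant against 42.0 ± 2.26 CPM in Col-0 (SD, n = 3), with counts of 720 to 802 against 860 to 950. Its log2 fold change was -0.15 with a standard error of 0.052 (edgeR quasi-likelihood, adjusted p = 0.0168). That call was lost with DESeq2 (adjusted p = 0.0786), without Col-0 library B at -0.11 (edgeR quasi-likelihood, adjusted p = 0.110) and without mutant library A at -0.13 (edgeR quasi-likelihood, adjusted p = 0.0843), and over all alternatives adjusted p ran from 0.00387 to 0.110. Of the 13 flavin metabolism genes, 3 were higher, 3 lower and 7 did not pass, or 2 higher and 3 lower adjusted over the list alone (camera, adjusted p = 0.731). FHY1 had -0.46, RIBA3 0.42 and RIBA2 -0.24. PyrD and AT2G20690 passed with 0.14 each, but not with DESeq2 (adjusted p = 0.163 and 0.104, from 0.0291 to 0.275 and from 0.0166 to 0.234 over the alternatives) or with upper quartile scaling, and PyrD also not without a filter on low counts, with a mean count of at least 50 or with all 9 libraries in 1 fit. With limma-trend on length-scaled counts they had 0.08 each, and AT2G20690 had 0.07 with the trend on GC content and transcript length removed, none of these called. Nor did they pass without Col-0 library B at 0.15 and 0.13, Col-0 library C at 0.11 and 0.10, mutant library A at 0.13 and 0.12 or mutant library B at 0.12 and 0.12. Of the 7 flavoprotein photoreceptors, 1 rose and PHOT1 fell, with a log2 fold change of -1.04 (edgeR quasi-likelihood, adjusted p = 2.38e-19), and the list was not called (camera, adjusted p = 0.250), with a median and a mean of opposite sign.

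In the jasmonate list, AOC2 (AT3G25770), an allene oxide cyclase of jasmonate synthesis, fell from 23.45 ± 1.60 to 2.45 ± 0.19 CPM, a log2 fold change of -3.26 (edgeR quasi-likelihood, adjusted p = 2.09e-20). Its paralog AOC1 had only -0.58, and reads of AOC1 and AOC2 are uncertain in their assignment. LOX2, also of jasmonate synthesis, had -0.33. MYC2, the main transcription factor of the pathway, had -1.14 and JAZ1, a repressor of it, -1.11. Only JAR1, which conjugates jasmonate to isoleucine, was higher (0.12), and the other 1 of the 19 did not pass (camera, adjusted p = 4.10e-19; adjusted p = 0.0382 with an estimated correlation). AOC2 was among the 6 lowest log2 fold changes of called, non-overlapping genes with a mean of at least 100 counts in the higher group, and the others were those of BAM5, a beta-amylase, at -4.23, the N-acetyltransferase NATA1 at -3.81, PIL1 at -3.69, the methyltransferase FAMT at -3.56 and CORI3, a cystine lyase, at -3.41. Reactive oxygen markers were lower in 8 of 11 cases and higher in 1, with a median of -0.49 (camera, adjusted p = 1.74e-07; adjusted p = 0.0435 with an estimated correlation).

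**Figure D3:**
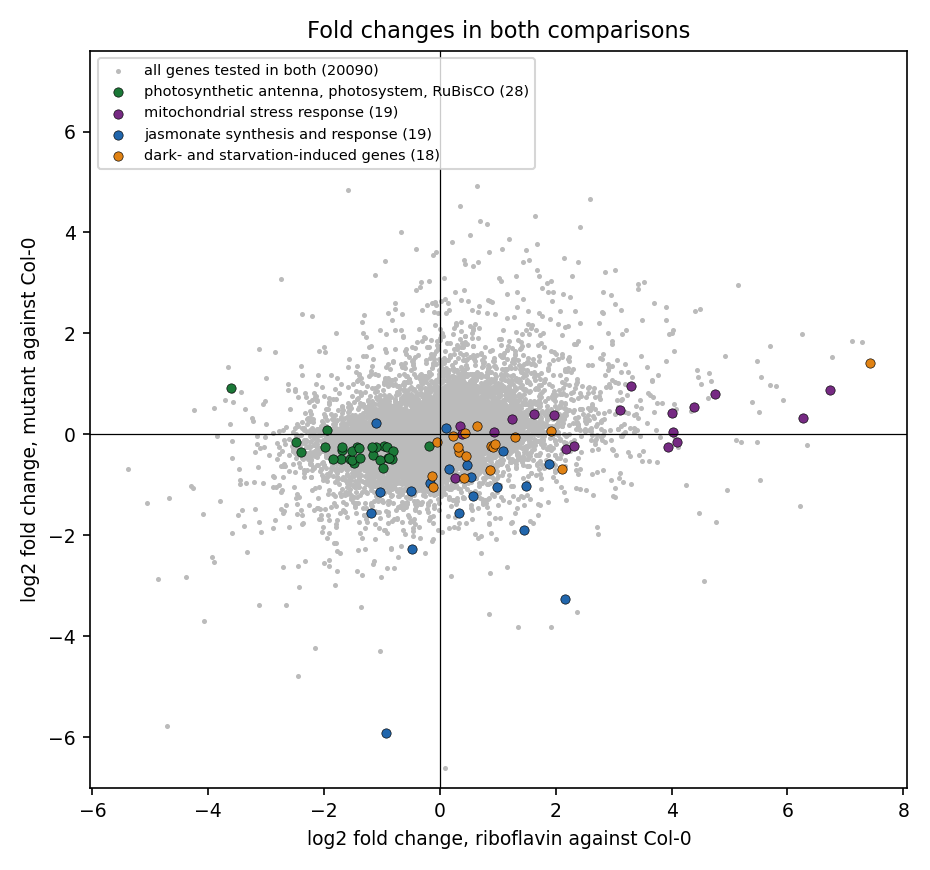
Log2 fold change against Col-0 in riboflavin (horizontal) and mutant (vertical) seedlings for the 20090 genes tested in both, with 4 gene lists coloured. The jasmonate genes lie mostly below the horizontal line, with 17 of 19 lower in the mutant, and the mitochondrial stress genes lie to the right, with 19 of 19 higher with riboflavin.

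Detoxification genes were higher in 14 of 18 cases and lower in 2, or 16 and 2 adjusted over the list alone (camera, adjusted p = 8.09e-10; adjusted p = 0.0435 with an estimated correlation). The glutathione S-transferases GSTF7, GSTF6 and GSTU8 rose by 2.36, 2.04 and 1.29, and reads of the close paralogs GSTF6 and GSTF7 are uncertain in their assignment. Salicylic acid and immunity genes were higher in 11 of 21 cases and lower in 4, with a median of 0.15 (camera, adjusted p = 0.00141; adjusted p = 0.0739 with an estimated correlation). FRK1, a flagellin-induced receptor-like kinase, rose by 4.01, from 3.95 ± 0.17 to 63.9 ± 1.90 CPM. The highest log2 fold changes among called, non-overlapping genes with a mean of at least 100 counts in the higher group were those of AT1G67270, a zinc-finger protein gene at 5.69, the peroxidase AT1G14550 at 4.92, the lipid-transfer protein gene AT4G12500 at 4.84, the berberine-bridge enzyme genes AT1G26390 and AT1G26410 at 4.65 and 4.33, and AT5G25260, a gene of a membrane protein with a Band 7 domain, at 4.52. The 2 berberine-bridge genes, and AT4G12500 with its neighbour, have close paralogs and their reads are uncertain in their assignment.

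Light-induced genes rose in 6 of 6 cases, with a median of 1.17 (camera, adjusted p = 0.00122; adjusted p = 0.0739 with an estimated correlation). HY5, the transcription factor that promotes photomorphogenesis, went from 13.5 ± 0.31 to 34.4 ± 1.74 CPM, a log2 fold change of 1.35, and its homolog HYH had 1.43 and RUP1, a repressor of UV-B signalling, 0.60. Photosynthetic genes nonetheless fell in 26 of 28 cases and rose in 2, with a median of -0.33 (camera, adjusted p = 2.05e-08; adjusted p = 0.163 with an estimated correlation). PSBQ-2 of photosystem II had -0.66 and the antenna gene LHCB4.2 -0.56, while RBCS1B had 0.92. Dark- and starvation-induced genes fell in 12 of 18 cases and rose in 2, DIN2 among these with 1.42, and the median was -0.24 (camera, adjusted p = 6.83e-05; adjusted p = 0.0734 with an estimated correlation).

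Heat shock genes were higher in 14 of 17 cases and lower in 1, with a median of 0.61 (camera, adjusted p = 4.95e-04; adjusted p = 0.0784 with an estimated correlation). AT1G53540 (HSP17.6C) rose by 2.27, HSP17.6A by 2.07 and HSP90.1 by 0.61. Abscisic acid and dehydration genes were lower in 11 of 17 cases and higher in 1, with a median of -0.56 (camera, adjusted p = 1.50e-04; adjusted p = 0.0739 with an estimated correlation). Auxin genes were lower in 13 of 20 cases and higher in 2, with a median of -0.27 (camera, adjusted p = 5.54e-04; adjusted p = 0.0739 with an estimated correlation). Glucosinolate genes were lower in 8 of 14 cases and higher in 3, with a median of -0.44 (camera, adjusted p = 2.26e-06; adjusted p = 0.0739 with an estimated correlation). The lower members of that list included CYP79F1 at -2.83 and MYB29 at -2.42, of the aliphatic branch, and the higher ones were CYP83B1, CYP79B2 and CYP79B3, of the indole branch, at 1.44, 1.117 and 0.73.

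Phosphate starvation genes were higher in 11 of 16 cases and lower in 3, or 12 and 3 adjusted over the list alone, with a median of 0.42 (camera, adjusted p = 7.25e-07; adjusted p = 0.0739 with an estimated correlation). Flavonoid and phenylpropanoid genes were higher in 8 of 15 cases and lower in 1, with a median of 0.29 (camera, adjusted p = 0.0252; adjusted p = 0.403 with an estimated correlation). Nitrate genes had 8 of 13 higher and 4 lower, led by the nitrate transport partner WR3 at 1.68 and the transcription factors HRS1 at 0.81 and LBD39 at 0.72, and were not called (camera, adjusted p = 0.0689) except without Col-0 library A (camera, adjusted p = 0.0497) or mutant library B (camera, adjusted p = 0.0450, with at most 0.106 when another library was left out). The mitochondrial stress list had 10 of 19 higher and 2 lower, or 10 and 3 adjusted over the list alone, and was not called (camera, adjusted p = 0.273); AOX1A rose by 0.54.

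Clock genes moved in both directions. Of the morning list, 5 of 8 were higher and 2 lower (camera, adjusted p = 0.220), with PRR9 at 0.83, RVE8 at 0.70, LHY at 0.53 and CCA1 at 0.42 against PRR7 at -0.62 and AT3G54500 (LNK2) at -0.54. Of the evening list, 4 of 8 were higher and 1 lower (camera, adjusted p = 0.296), with PRR5 at 2.00 and PCL1 (LUX) at 0.59. ELF4 at 0.64 was not called without mutant library B, where it had 0.42 (edgeR quasi-likelihood, adjusted p = 0.109, from 0.00115 to 0.109 over the alternatives). GI at 0.13 was not called with DESeq2 (adjusted p = 0.141, from 7.04e-04 to 0.415 over the alternatives), with upper quartile scaling, without a filter on low counts, with a mean count of at least 50, with limma-trend on length-scaled counts at 0.06, or without Col-0 library B at 0.09, Col-0 library C at 0.14, mutant library A at 0.11 or mutant library C at 0.10.

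Root hair markers fell in 6 of 6 cases, with a median of -0.76 (camera, adjusted p = 0.00257; adjusted p = 0.403 with an estimated correlation). The cell wall proteins PRP1 and PRP3 had -1.102 and -0.95 and the expansin EXPA7 -0.82. Endodermis and root tip markers were lower in 5 of 8 cases and higher in none, with a median of -0.37, and were not called (camera, adjusted p = 0.220). Stomatal lineage markers were higher in 4 of 7 cases (camera, adjusted p = 0.344), and of 5 seed storage genes 3 were higher and 1 lower (camera, adjusted p = 0.338). The seed storage median of 1.402 was the largest of any list in the mutant, but the 3 higher members, SESA1, SESA2 and SESA3, had means of only 0.87, 1.11 and 0.91 CPM there. These root markers were lower in the same libraries in which the photosynthetic, jasmonate, abscisic acid and auxin lists were lower.

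In the mutant, camera called 14 of 31 lists, 6 higher and 8 lower, and the calls of jasmonate, reactive oxygen and detoxification genes held with an estimated correlation. Adjusted over the list alone, counts were equal to those given for the other lists named. Median and test also differed in sign for iron deficiency genes, which were not called (camera, adjusted p = 0.287). The groups did not overlap in 56.7% of genes tested, where chance gives 10%. The authors' deposited table has 7989 genes at a q-value under 0.05, and 7903 of the genes called here are among them, with no opposite sign.

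**Figure D4:**
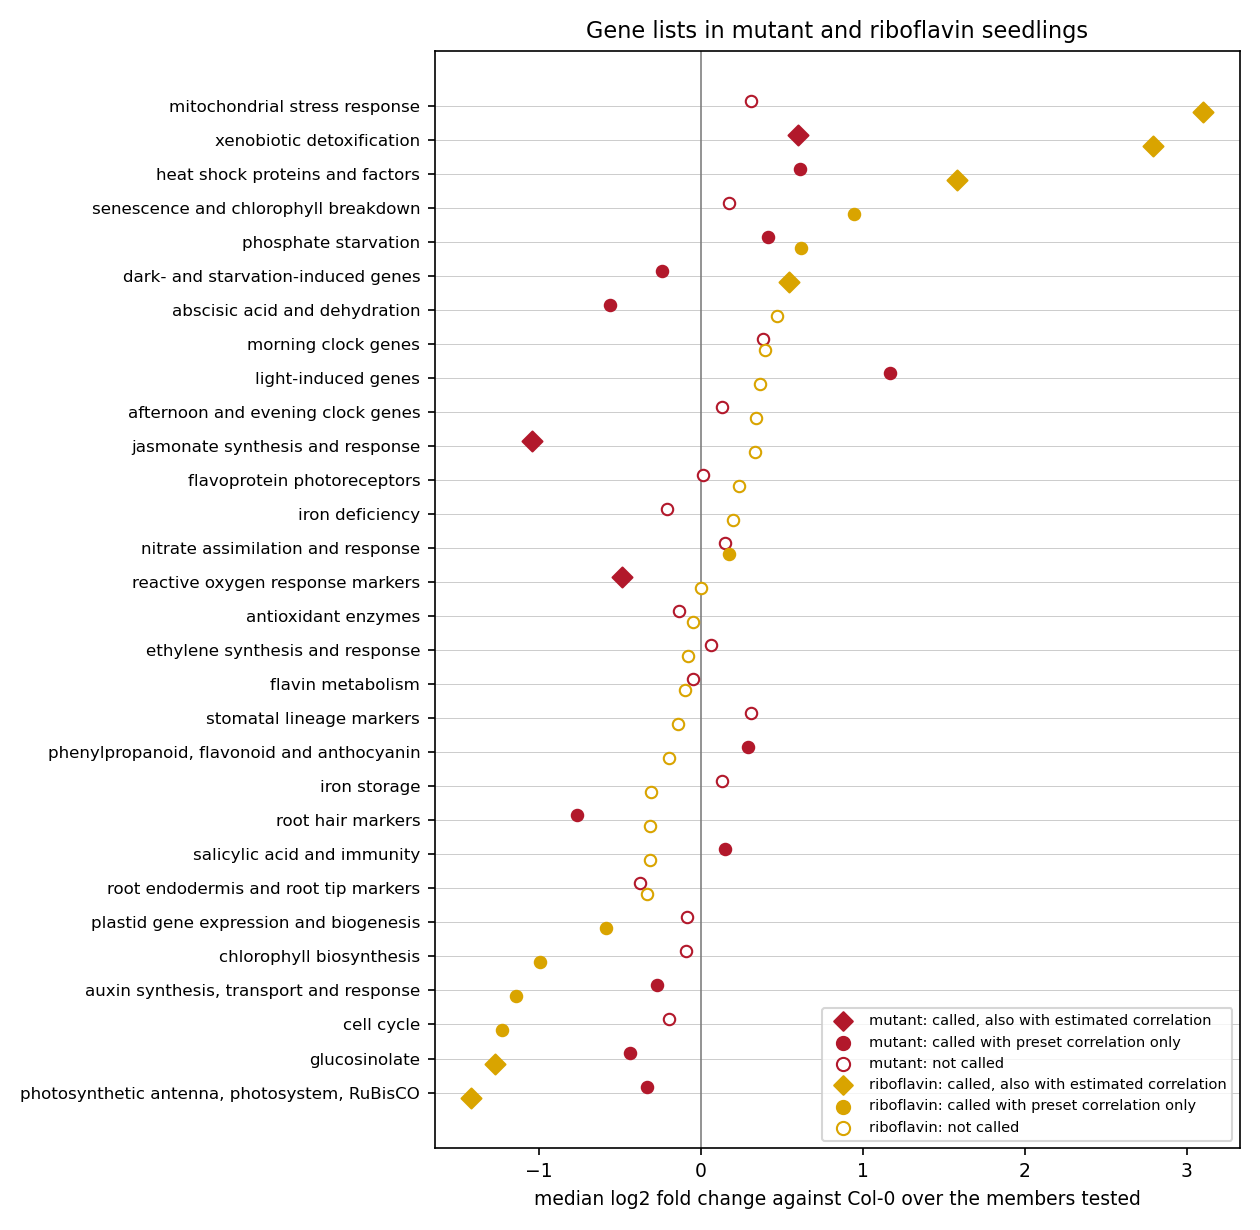
Median log2 fold change of each gene list tested in both comparisons with Col-0, in mutant and riboflavin seedlings. Diamonds are lists called by camera also with an estimated correlation (3 in the mutant, 6 with riboflavin), filled circles are called with the preset correlation only, and open circles are not called.

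The direct comparison of the mutant with riboflavin-treated Col-0 tests the difference between the 2 responses without using the Col-0 controls. Compared with treated seedlings, mutant seedlings had lower mitochondrial stress and detoxification transcripts, lower jasmonate and dark-induced transcripts, and higher photosynthetic and chlorophyll transcripts. All 19 mitochondrial stress genes were lower, with a median log2 fold change of -2.54 (camera, adjusted p = 1.71e-42; adjusted p = 0.00474 with an estimated correlation). Of 20344 genes tested, 7556 were higher and 7527 lower in the mutant, of which 1955 at least doubled and 1512 at least halved (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The share of calls that were higher was 50.1%, and it was 54.9% with upper quartile scaling and 46.9% with limma-trend on length-scaled counts. FMN/FHY was lower by a log2 fold change of -1.58, with a standard error of 0.043 (edgeR quasi-likelihood, adjusted p = 8.36e-24).

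Detoxification genes were lower in 17 of 19 cases and higher in 2, with a median of -2.45 (camera, adjusted p = 1.96e-42; adjusted p = 0.00349 with an estimated correlation). Jasmonate genes were lower in 17 of 19 cases and higher in 1, with a median of -1.43 (camera, adjusted p = 3.80e-12; adjusted p = 0.00955 with an estimated correlation). Dark- and starvation-induced genes were lower in 18 of 18 cases, with a median of -1.03 (camera, adjusted p = 1.58e-20; adjusted p = 0.00955 with an estimated correlation). Photosynthetic genes were higher in 27 of 28 cases, with a median of 0.95 (camera, adjusted p = 8.58e-28; adjusted p = 0.00955 with an estimated correlation). Chlorophyll biosynthesis genes were higher in 19 of 20 cases, with a median of 1.06 (camera, adjusted p = 7.22e-14; adjusted p = 0.0348 with an estimated correlation).

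Glucosinolate genes were higher in 14 of 14 cases, with a median of 0.85 (camera, adjusted p = 1.52e-06; adjusted p = 0.0638 with an estimated correlation). Cell cycle genes were higher in 16 of 17 cases, with a median of 1.07 (camera, adjusted p = 9.79e-04; adjusted p = 0.108 with an estimated correlation). Salicylic acid and immunity genes were higher in 15 of 21 cases and lower in 4, with a median of 1.02 (camera, adjusted p = 0.0130; adjusted p = 0.127 with an estimated correlation). Plastid gene expression was higher in 9 of 14 cases and lower in 4 (camera, adjusted p = 0.0225; adjusted p = 0.127 with an estimated correlation). Abscisic acid genes were lower in 16 of 17 cases, with a median of -1.21 (camera, adjusted p = 2.39e-04; adjusted p = 0.0579 with an estimated correlation). Senescence genes were lower in 8 of 8 cases (camera, adjusted p = 2.45e-06; adjusted p = 0.0786 with an estimated correlation). Heat shock genes were lower in 14 of 17 cases, or 15 adjusted over the list alone, and higher in 2 (camera, adjusted p = 2.05e-05; adjusted p = 0.0816 with an estimated correlation).

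The highest log2 fold changes among called, non-overlapping genes with a mean of at least 100 counts in the higher group were those of the paralogous lipid-transfer protein genes AT4G12500 and AT4G12490, at 6.42 and 5.81, followed by WRKY49 at 4.81, the oxygenase AT2G36690 at 4.76 and FRK1 at 4.67. The lowest were those of BGLU28 at -8.80, AT1G09500, a gene of an NAD(P)-binding protein, at -7.64, the oxygenase AT2G38240 at -7.48, SUC7 at -6.59 and the cinnamyl alcohol dehydrogenase ELI3-2 at -6.57. PHOT1 had 0.35 and AOC2 -5.43. Seed storage genes were higher in 4 of 5 cases, with a median of 3.63, and were not called (camera, adjusted p = 0.355). Camera called 13 of 31 lists, 6 higher and 7 lower, and 6 of these calls held with an estimated correlation. Adjusted over the list alone, the other counts given were equal, and 5 in place of 4 genes were lower among root hair markers and among evening clock genes, which were not called. Median, mean and test differed in sign for ethylene, iron storage, phosphate starvation and root tip genes, none of which was called. The groups did not overlap in 75.4% of genes tested, where chance gives 10%.

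The mutant and riboflavin responses shared more genes in the same direction than independent responses would. Of 20090 genes tested in both, 2750 were higher and 2893 lower in both, where independent lists of these sizes would share 1836 and 1932. Opposite directions were fewer: 1289 genes were higher in the mutant and lower with riboflavin, where 1913 would be shared by independent lists, and 1238 were lower in the mutant and higher with riboflavin, against 1855. Genes changed in both at least 2-fold numbered 251 higher in both, 182 lower in both, 47 higher in the mutant and lower with riboflavin, and 50 lower in the mutant and higher with riboflavin, where independent lists would share 45.5, 48.8, 66.4 and 33.5. At this 2-fold threshold, genes lower in the mutant and higher with riboflavin were thus more, not fewer, than independent lists would share. PIL1, PHOT1, CYP79F1 and MYB29 fell in both, while AOC2 fell in the mutant and rose with riboflavin. Across genes, log2 fold changes had a Pearson correlation of 0.308 and a Spearman correlation of 0.324, with a covariance of 0.136. Unchanged groups simulated with shared Col-0 libraries in 100 draws gave a mean correlation of 0.495 with a covariance of 0.0072, and called on average 0.02 genes higher in both. The observed correlation was thus lower, and the observed covariance higher, than in these draws. With no gene changed, almost no calls are made, so the draws do not measure how much overlap shared controls add to real responses. They also hold no difference of the Col-0 group in hour of collection or handling. The 3 Col-0 libraries cannot be split between the comparisons, so part of the excess may come from the shared controls.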

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

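The tests of the spread between libraries and of the number of genes called in other splits were chosen only after the results were seen, as were the reading of the root markers beside the photosynthetic genes and the use of the SD of the light-induced and photosynthetic genes; the light-response terms were also read then.

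The dark- and starvation-induced genes stand out because camera called them in opposite directions in the comparisons with Col-0 and also called them in the direct comparison. The direct test was thus part of the selection. It measures the difference of the same comparisons with Col-0, so it adds no separate support. Jasmonate, abscisic acid, salicylic acid, flavonoid and reactive oxygen genes also had medians of opposite sign. These lists were called in the mutant but not with riboflavin. The dark- and starvation-induced genes had a median log2 fold change against Col-0 of -0.24 in the mutant and 0.55 with riboflavin. With an estimated correlation their call held with riboflavin (camera, adjusted p = 0.0261) and was lost in the mutant (camera, adjusted p = 0.0734). The direct comparison gave a median of -1.03 for mutant minus riboflavin, with 18 of 18 genes lower (camera, adjusted p = 1.58e-20; adjusted p = 0.00955 with an estimated correlation).

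With riboflavin, 15098 of 20356 genes were called. The clock genes moved no more than other genes, which cannot decide whether seedlings were collected at another time of day. The median absolute log2 fold change of the 16 clock genes was 0.404, at percentile 54.0 of 10000 random lists of like expression. Morning and evening medians had the same sign (0.39 and 0.34). The random lists came from the same comparison and had a median of 0.391, so a broad response of any cause would hide a shift of the clock. With a trend on GC content and transcript length removed, 96.2% of the 3591 genes that at least doubled or halved kept that call, which argues against such a bias. A collection in the dark against Col-0 in the light stays open: the median of light-induced genes was 0.37, above 0 by less than its SD of 0.75 over 5 members, while dark-induced genes rose and genes annotated to red, far red and blue light responses, many of them antenna and RuBisCO genes, had medians of -1.51, -1.50 and -1.404, with photosynthesis genes at -1.13. A response to riboflavin and an effect of handling also stay open, since the labels name no mock treatment.

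In the mutant, 10254 of 20277 genes were called. A different time of collection cannot be told apart from the genotype: the median absolute log2 fold change of the clock genes was 0.477, at percentile 99.99 of random lists with a median of 0.172, but morning and evening medians, 0.39 and 0.13, did not oppose each other. A smaller share of root stays open by the rule written beforehand. Root hair markers (median -0.76) and endodermis and root tip markers (median -0.37, 5 of 8 lower, list not called) both had lower medians as it needs. Photosynthetic genes, which it would raise, were lower in 26 of 28 cases (median -0.33, SD 0.286). Read afterwards, this argues against it only as the whole cause. Neither the root hair nor the photosynthetic list was called with an estimated correlation (camera, adjusted p = 0.403 and 0.163). A chromosome segment linked to FMN/FHY that differs from Col-0 stays open: 7.12% of 815 genes within 2 Mb at least doubled or halved against 6.02% elsewhere (Fisher's exact test, one-sided p = 0.115; odds ratio 1.196, 95% interval 0.893 to 1.57). The lesion in FMN/FHY is the biological explanation in the design and was not tested apart from these. No other mutant line was sampled, so that lesion cannot be told apart from other differences between this EMS-mutagenised line and Col-0.

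Libraries of a group were close to each other. The largest biological coefficient of variation among genes with a mean count of at least 500 was 0.0354, in Col-0, against 0.0319 in the mutant and 0.0305 with riboflavin. Repeat libraries of 1 RNA sample were taken to need less than 0.02 in each group and separate plants more than 0.05 in some group, so this value leaves it open. Squared differences between pairs of libraries were 2.68 to 4.46 times those of counting error, per gene. The labels call the replicates biological, and no biological explanation was tested.

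Other splits of the 6 libraries number 10 with the real split, too few for a share under 0.05. For mutant against Col-0, 1 split gave as many genes, the real split itself with 10254, and the highest of the others gave 0. The same held for riboflavin against Col-0, with 1 split and 15098 genes against 0, and for mutant against riboflavin, with 1 split and 15083 genes against 0. For lists, mutant against Col-0 had 14 called and at most 10 in another split, with 1 split as high. Riboflavin against Col-0 had 13 called and 14 in another split, with 3 splits as high, and mutant against riboflavin had 13 called and 14 in another split, with 7 splits as high. A mixed split retains part of the group difference on both sides, and camera ranks genes even where no gene is called.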

How the results depend on the processing

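The fits with a trend on GC content and transcript length removed and with limma-trend on length-scaled counts were chosen only after the data were seen. Of the genes and lists put to the alternatives, none was called in the opposite direction, but whether more calls were higher or lower depended on the scaling. Among results that answer a comparison, 182 values stayed on the same side of the threshold or within 1.5 times, 16 moved and 3 were weaker, and among single genes and lists 2462 stayed, 51 became stronger and 55 weaker. A minimum of 1 in log2 fold change left, by its construction, 744 higher and 486 lower genes in the mutant, 1567 and 2024 with riboflavin, and 1955 and 1512 in mutant against riboflavin, and in the overlap 251, 182, 47 and 50. Camera with an estimated correlation called 3, 6 and 6 lists in the 3 comparisons and fry 31, 29 and 28, since fry tests the list alone and not against other genes. FMN/FHY in the mutant was -0.15 with DESeq2 (DESeq2, adjusted p = 0.0786, in a range of 0.00387 to 0.110 over the alternatives) and -0.18 to -0.11 when a library was left out; the cause was not tested. DESeq2 called 8161, 13743 and 13613 genes and the replicate block 10427, 15033 and 15092. The share of calls that were higher was 50.2% in the mutant, 46.8% with upper quartile scaling and 39.4% with limma-trend on length-scaled counts. With riboflavin it was 49.6%, from 44.5% with upper quartile scaling to 51.0% with the trend on GC content and length removed, and in mutant against riboflavin 50.1%, from 46.9% with limma-trend to 54.9% with upper quartile scaling; the cause was not tested. Pseudocounts were not varied, since the tables hold counts. In data simulated from mutant and Col-0 libraries 88% of 1.5-fold changes were recovered, so genes not called are not shown to be unchanged.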

Other observations

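The process terms and the chromosome windows below were chosen only after the results were seen. Terms were read from the annotation, which lists only a number of processes for many genes, so the sets are incomplete.

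In the mutant, genes annotated to defense response to fungus were higher in 39 of 58 cases and lower in 11, with a median log2 fold change of 0.30 (camera, adjusted p = 4.05e-18; adjusted p = 0.178 with an estimated correlation). Genes of starch catabolism, among them beta-amylases, were lower in 11 of 11 cases, with a median of -0.48 (camera, adjusted p = 2.07e-06; adjusted p = 0.273 with an estimated correlation). With riboflavin, genes of fatty acid biosynthesis were lower in 32 of 43 cases and higher in 5, with a median of -0.72 (camera, adjusted p = 9.99e-06; adjusted p = 0.153 with an estimated correlation). Genes of microtubule-based movement, mostly motor proteins, were lower in 40 of 45 cases with riboflavin (camera, adjusted p = 1.51e-04; adjusted p = 0.164 with an estimated correlation) and in 25 of 44 in the mutant (camera, adjusted p = 0.0412; adjusted p = 0.621 with an estimated correlation).

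Ribosome biogenesis moved in opposite directions. Of its 100 genes, 67 were higher and 9 lower in the mutant (camera, adjusted p = 0.01001; adjusted p = 0.784 with an estimated correlation), and 19 were higher and 67 lower with riboflavin (camera, adjusted p = 1.70e-04; adjusted p = 0.295 with an estimated correlation). The direct comparison placed them higher in the mutant (camera, adjusted p = 2.44e-09; adjusted p = 0.258 with an estimated correlation). Of 247 or 248 terms tested in a comparison, none of those named here was called with an estimated correlation.

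In windows of 2 Mb, the share of tested genes that at least doubled or halved in the mutant was 11.6% of 215 genes on chromosome 5 from 14 Mb, 10.3% of 322 genes on chromosome 4 from 6 Mb and 9.56% of 450 genes on chromosome 2 from 16 Mb (Fisher's exact test, one-sided, adjusted p = 0.0472 for each). The test treats neighbouring genes as independent, which close paralogs side by side are not. AT4G12500, which has such a neighbour, lies in the chromosome 4 window.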
